A study of Arabidopsis thaliana with 20 samples.

How the data were processed

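The values analysed are the deposited log ratios of 20 two-colour arrays, 1 column per array, and no scanner files were used. Per the labels' protocols, RNA was amplified by in vitro transcription and coupled to Cy3 or Cy5, and 2 consecutive days of the same tissue set shared an array. The background correction, the normalization, the log base, the numerator of the ratios and the genome build behind the annotation are not given in the sources used here. The deposited values were read as log10 ratios, because on every array they stop exactly at 2 and -2, which is 100-fold on that scale. Array medians lay between -0.00333 and 0.0120 and interquartile ranges between 0.0986 and 0.191. The arrays had therefore likely been centred before deposit, by a step that stays unknown. Between 436 and 827 probes per array stood at the upper limit and 1 to 31 at the lower one, and such values were kept. The table names neither signal nor background, so no probe was left out as dim, and a fold can be no larger than its limit allows within 1 array.

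The direction of the ratios had to be worked out. All 416 probes that stood at a limit on 15 or more arrays were at the upper limit under both dye assignments. As deposited, arrays of the same interval and opposite dye assignment had a median correlation across features of 0.132, with 17 of 20 pairs above 0. This sign alone would be read as values already turned to the later day. It includes, however, what each feature shares over all 20 arrays. After subtracting each feature's mean over 20 arrays, the median for the same pairs was -0.294, with 2 of 20 above 0. The subtraction alone cannot decide, because a dye bias in values already turned could also give a correlation below 0. Read as turned, however, the 416 probes at the upper limit would have risen 100-fold or more on most arrays. For these probes this argues against values already turned. The values were therefore taken to follow the dyes. They were taken as Cy5 over Cy3, an assumed channel order, because the labels do not say which channel is the numerator. Arrays with the later day in Cy3 were turned. The planned check of the remaining sign with AP3, PI, AG and SEP3 could not be made because no probe carries these names, so the direction is called likely. It rests on the channel order and on genes looked at after the values were seen: AGL24, FD, AGL71 and AGL72, known from inflorescence meristems, were lower by day 5, and JAG, RBE and SPL/NZZ, known from floral organs, were higher. These genes are then no independent evidence of direction.

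Of 30741 spots in the table, 547 control or unannotated spots were left out. Of the 30194 probes left, 18740 had 1 gene name in the platform annotation, 1 had several and 11453 had none, and the named probes stood for 17197 genes. Through the RefSeq gene table of TAIR10.1, which was used for names alone, 18645 probes were matched and 95 kept the older name. Named probes were uneven: 15.5% of protein-coding loci with a symbol had one, against 82.1% of those without a symbol, so many well-known genes are unnamed here. Probes of 1 gene were averaged; 1429 genes had more than 1 probe, and in 14 of them at least 2 probes passed the test in 1 interval, with opposite directions in 1 gene, INO. A feature needed values on at least 3 of 4 arrays of every interval, which kept 28633 features, and sums over a set needed at least 3 sets, which kept 28615.

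Each interval was tested with limma 3.58.1 in R 4.3.3, in a fit to all 20 arrays with 5 interval coefficients and 1 dye coefficient per feature. It left 14 residual degrees of freedom and used 2.07 prior ones. Day 5 against day 0 used the sum of the 5 ratios within each set, 4 values with 3 residual and 1.72 prior degrees of freedom. F tests asked whether a feature changed in any interval and whether its change differed between intervals. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists for organ identity, inflorescence and flowering time, shoot meristem and boundary, organ growth and polarity, stamen and anther, carpel and ovule, mitotic cell cycle, DNA replication, auxin, gibberellin, cytokinin, jasmonate, photosynthesis, flavonoids, vascular tissue, epidermis and stomata, heat shock, touch and wounding, the circadian clock and reference genes were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data. A list needed at least 3 measured genes, and 54 list tests were adjusted together.

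The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule names, among calls with 1 gene name and the same sign in every set, the 6 largest rises and 6 largest falls of each interval, 10 and 10 for day 5 against day 0, and up to 4 called genes of each list. FAMA, AUR1, AUR2, HSP22, GI, TIP41, EF1A and the uncalled list members fall outside it and are given as values of fixed lists. The alternatives chosen then were no dye coefficient, arrays centred or scaled, other missing-value rules, each probe tested alone, robust eBayes, the set as a block, each set left out, the 4 arrays of an interval alone, a minimum of 1.5-fold, the sum of the interval coefficients, a dye term on the sums and an estimated correlation. Values at the limits left out, a dye coefficient for each interval, calls with the same direction in every set and the block in the list tests were chosen after seeing the data.

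The series' design text says that the sets are independent tissue collections, so set numbers pair arrays, and neighbouring arrays of a set share a tissue sample. Deviations from the interval means had a median correlation across features of -0.0833 (-0.164 to 0.152) over 16 neighbouring pairs of 1 set, against 0.0391 over 48 neighbouring pairs of different sets. The fits treat arrays as independent, and this was tested on simulated data with the real spread of each feature and 50 of 28633 features changed by each of 4 fold sizes from day 0 to day 1. The test recovered 39 of 50 changes of 2-fold and 49 of 50 of 4-fold when all noise was carried by the samples, and 40 and 49 when it was separate for each array. Of the calls, 11.8% were false with noise carried by the samples and 3.42% with separate noise, and for the test of differences between intervals 50.5% and 5.75%. The residuals of neighbouring arrays in a set had a median correlation per feature of -0.110 in the deposited values. This lies between -0.393 with noise carried by the samples and 0.0744 with separate noise. The simulated shares of false calls come from 1 draw of each kind, few changed features and noise drawn independently between features. They therefore do not bound the share in the deposited values. For the sums of day 5 against day 0, which share no tissue between sets, 29 of 50 simulated changes of 4-fold and 0 of 50 of 2-fold were recovered with noise carried by the samples (28615 features), and 0 of 50 of 4-fold with separate noise.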

Results

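Relative transcript levels were measured on 20 two-colour microarrays in Arabidopsis thaliana plants that lack the floral regulators AP1 and CAL and carry AP1 fused to the hormone-binding part of a glucocorticoid receptor (35S:AP1-GR ap1 cal). Such plants form inflorescence-like meristems in place of flowers, and 1 µM dexamethasone activates the fusion protein so that flowers begin together. Tissue was taken on days 0, 1, 2, 3, 4 and 5 after activation in 4 independent sets, with 25 plants per time point. Each array compared 2 consecutive days of 1 set, which gave 4 arrays for each of the 5 intervals, 2 with the later day in Cy5 and 2 with it in Cy3. Each array gave a value for 30142 to 30180 of 30194 probes, and the number of arrays, not a read depth, limits the precision. After averaging the probes of a gene, 28633 features were tested, of which 17185 carried 1 gene name and the others stayed unnamed probes. Changes are log10 ratios of the later over the earlier day, where log10 is a reading of the values and the direction is the likely one, both for reasons given with the processing. The floral regulators AP1, LFY, TFL1, AP3, PI, AG and SEP3 are not analysed here, because no probe carries their names.

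**Figure D1:**
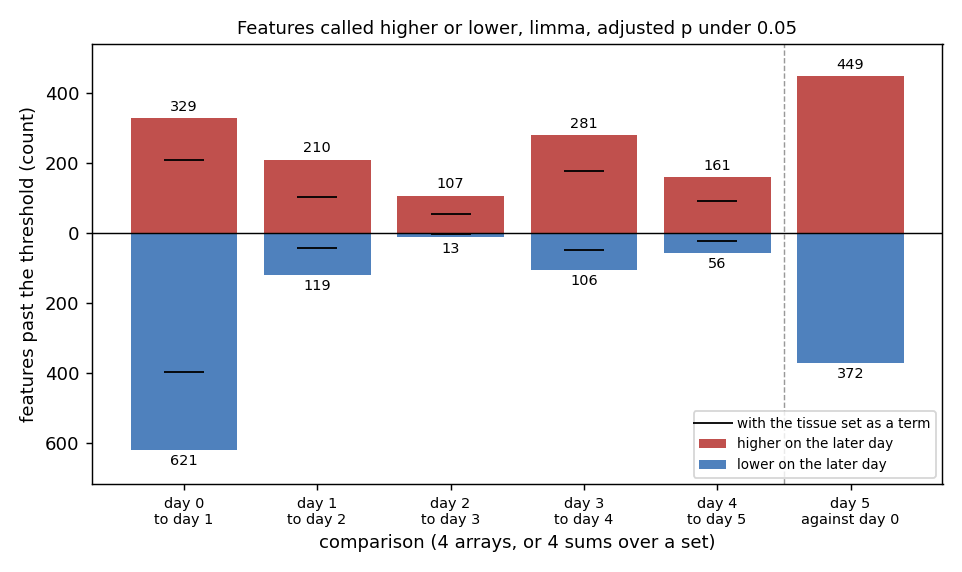
Count of features called higher (upward bars) or lower (downward bars) in each of 5 intervals and for day 5 against day 0, by limma at an adjusted p under 0.05; black marks give the counts with the tissue set as a term, where that fit exists. The bars of day 0 to day 1 show 329 higher and 621 lower features, and those of day 2 to day 3 show 107 higher and 13 lower.

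The interval from day 0 to day 1 holds the earliest changes measured after AP1 activation. No set without dexamethasone was analysed here, so a response to AP1 cannot be told apart from other effects of treatment or time. SWEET1 (AT1G21460), a sugar transporter gene, rose 10.1-fold, a log10 change of 1.00 ± 0.074 (SD, n = 4, adjusted p = 6.99e-09), and AT3G51660, of the macrophage migration inhibitory factor family, rose 6.72-fold (0.83 ± 0.065, adjusted p = 6.99e-09). Genes of the inflorescence and flowering time list fell: FD, a bZIP partner of the flowering signal, was lower by a factor of 2.49 (-0.40 ± 0.093, adjusted p = 1.61e-04), and the MADS-box genes AGL72, AGL42 and AGL71 by factors of 2.18, 1.82 and 1.66. The petal and organ growth genes RBE and JAG, both zinc-finger regulators, rose 3.28-fold (0.52 ± 0.11) and 2.24-fold (0.35 ± 0.046), and UFO, an F-box gene of organ identity, rose 1.99-fold (0.30 ± 0.13, adjusted p = 8.14e-04). DFR, an enzyme of anthocyanin synthesis, fell 2.35-fold (-0.37 ± 0.26, adjusted p = 0.0233, and 0.0585 with the set as a block).

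In this interval 950 features passed the test, 329 higher and 621 lower, among them 511 with a gene name. Among named genes with the same direction in every set, the other large rises were AT5G22430 (8.53-fold), AT2G42885 (5.48-fold), AT1G47610 (5.47-fold) and AT3G30620. The rise of AT3G30620, 5.13-fold on average, rested on 1 dye assignment: its log10 changes were 1.55 and 1.16 in sets 1 and 3 and 0.053 and 0.083 in sets 2 and 4. The large falls among such genes were AT4G11190 (5.10-fold), AT1G75900, a lipase family gene (4.24-fold), AT3G11680 (4.18-fold), AT1G31710 (4.06-fold), AT3G13130 (3.96-fold) and AT5G48430 (3.74-fold). Of the 7 measured genes of the inflorescence and flowering time list, 4 fell over all genes tested and 5 fell adjusted over the list alone, and AGL24 measured -0.21 (adjusted p = 0.0829). The list was lower as a group in limma's camera test (adjusted p = 8.22e-06, adjusted p = 0.0814 with an estimated correlation). Of the 7 measured genes of organ growth and polarity, 2 rose over all genes, while 2 rose and 1 fell adjusted over the list alone. The list was higher as a group (adjusted p = 0.00523, adjusted p = 0.146 with an estimated correlation). In the auxin list GH3.3, which conjugates auxin to amino acids, rose 1.51-fold (adjusted p = 0.00918), the 1 gene of 7 that rose over all genes and adjusted over the list alone. This call of GH3.3 was lost without set 1, 2 or 3 and without a dye coefficient. Its calls from day 2 to day 3 and day 3 to day 4 were also lost without a dye coefficient. The list did not pass as a group (adjusted p = 0.501). With the tissue set as a block 605 features passed, and without sets 1, 2, 3 and 4 in turn 349, 195, 1040 and 341 passed, with 46.7% higher in place of 34.6% when set 2 was left out. With the direction turned these would be shares of lower calls. With limma on the 4 arrays of this interval alone 0 passed, against 3537 at an unadjusted p under 0.05.

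From day 1 to day 2 RBE and JAG rose further. RBE rose 3.83-fold (0.58 ± 0.11, adjusted p = 1.59e-04), YAB3, a gene of organ polarity, rose 2.17-fold (0.34 ± 0.16, adjusted p = 0.00545) and JAG rose 1.98-fold (0.30 ± 0.12, adjusted p = 0.00409). REM22, a B3-domain gene, rose 5.47-fold (0.74 ± 0.13, adjusted p = 2.87e-04) and FLP1, related to a flowering-promoting factor, 4.42-fold (0.65 ± 0.085, adjusted p = 0.00113). Among the genes that fell were PUCHI, an AP2-domain regulator of floral meristem identity, by a factor of 3.00 (-0.48 ± 0.10, adjusted p = 0.00755), and 2 genes whose calls were lost with the set as a block: SWEET11, a sugar transporter gene (2.34-fold, adjusted p = 0.0423, and 0.106 with the block) and the defensin gene PDF1.2c (2.34-fold, adjusted p = 0.0333, and 0.0892 with the block).

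This interval had 329 calls, 210 higher and 119 lower, 168 of them with a gene name. AT4G16550 rose 5.23-fold and AT5G57720 3.41-fold, and AT4G18080 and AT4G17990 fell 2.53-fold and 2.42-fold. Among named genes the largest rise and the largest fall rested on values at the limit of the scale on 2 arrays of 1 dye assignment. AT2G14415 rose 13.1-fold on average, from 0.40, 2.0, 0.07 and 2.0 in sets 1 to 4, and AT1G51890 fell 10.3-fold on average, from -2.0, -0.05, -2.0 and -0.01. Of the organ growth and polarity list 3 of 7 genes rose over all genes and 4 adjusted over the list alone (camera adjusted p = 6.27e-07, adjusted p = 0.0239 with an estimated correlation), the list test that also passed with that correlation. Of the inflorescence and flowering time list 0 of 7 genes fell over all genes by limma (3 at an unadjusted p under 0.05), with 3 adjusted over the list alone, and the list was lower as a group (adjusted p = 0.0234, adjusted p = 0.257 with an estimated correlation). SHI, of the carpel and ovule list, rose 1.42-fold (0.15 ± 0.081, adjusted p = 0.0296, and 0.0892 with the block), though set 1 measured 0.030 against 0.18 to 0.20 in the others. IAA30, of the auxin list, rose 1.41-fold (adjusted p = 0.0401, and 0.113 with the block). Of these lists 1 of 6 carpel and ovule genes and 1 of 7 auxin genes were called over all genes, while 1 carpel and ovule gene and 3 auxin genes, 2 higher and 1 lower, were called adjusted over the list alone. With the set as a block 147 features passed, with arrays scaled to 1 spread 140 did, AT4G17990, PDF1.2c, SWEET11, SHI and IAA30 no longer among them, and without sets 1, 2, 3 and 4 in turn 67, 0, 341 and 50 passed in limma. Without set 2 3477 features had an unadjusted p under 0.05, and 5 features passed when the 4 arrays were fitted alone.

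From day 2 to day 3 nearly all calls were rises in the likely direction of the ratios. With the direction turned nearly all would be falls. NGA3, a B3-domain gene of gynoecium development, rose 3.13-fold (0.50 ± 0.094, adjusted p = 9.98e-05), REM22 rose 3.27-fold (0.51 ± 0.11, adjusted p = 0.00455), and AT1G15260 rose 3.76-fold (0.58 ± 0.17, adjusted p = 4.80e-04). GH3.3 rose 1.62-fold (0.21 ± 0.11, adjusted p = 0.0127, and 0.0577 with the set as a block). Of 120 features called, 107 were higher and 13 lower, and 58 carried a gene name.

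The other large rises of this interval were AT5G16030 (2.90-fold), AT4G16270 (2.88-fold) and AT4G18970 (2.75-fold). Among the falls AT1G42375 fell 2.16-fold, AT3G60960 1.63-fold and AT4G15765 1.54-fold, and 3 more were lost with the set as a block, AT3G13950 (1.77-fold, adjusted p = 0.0441, and 0.102 with the block), LOJ (1.55-fold; 0.0357, and 0.0736) and AT5G43870 (1.45-fold; 0.0426, and 0.129). Of the 6 measured genes of the carpel and ovule list NGA3 alone rose over all genes and 3 rose adjusted over the list alone. The list was higher as a group in the camera test (adjusted p = 2.20e-04, adjusted p = 0.0814 with an estimated correlation). INO, 1 of the 6, entered as the mean of probes that measured 0.132, 0.194 and -0.028. The organ growth and polarity list was higher as a group (adjusted p = 0.0151, adjusted p = 0.166 with an estimated correlation) with 0 of 7 genes called over all genes by limma (3 at an unadjusted p under 0.05) and 3 adjusted over the list alone. YAB3 measured 0.24 (adjusted p = 0.0664) and JAG 0.14 (adjusted p = 0.356). With arrays scaled REM22, AT4G16270 and AT3G13950 lost their calls. With the block 57 features passed, and without sets 1, 2, 3 and 4 in turn 24, 0, 193 and 22 passed in limma, with 1623 at an unadjusted p under 0.05 without set 2. When the 4 arrays were fitted alone 6 features passed, all of them lower.

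From day 3 to day 4 DFR, MUTE and ARR16 rose, single genes of lists with too few measured genes to be tested as groups. DFR rose 4.95-fold (0.69 ± 0.11, adjusted p = 3.73e-04), and AT4G22870, an oxygenase family gene, 6.80-fold (0.83 ± 0.034, adjusted p = 3.67e-04). MUTE, a bHLH gene of stomatal precursors and a marker of another cell type, rose 5.08-fold (0.71 ± 0.19, adjusted p = 4.24e-04), and ARR16, a cytokinin response regulator, 4.66-fold (0.67 ± 0.20, adjusted p = 0.00425). YUC6, an enzyme of auxin synthesis, rose 2.11-fold (0.32 ± 0.095, adjusted p = 0.00124), GH3.3 1.85-fold (0.27 ± 0.14), NGA3 2.67-fold (0.43 ± 0.044) and SPL/NZZ, a gene needed to start sporocytes, 1.45-fold (0.16 ± 0.081, adjusted p = 0.00709). AGL71 and AGL72 fell by factors of 1.86 and 1.77, and UFO by a factor of 1.54 (-0.19 ± 0.080, adjusted p = 0.0427, and 0.0811 with the set as a block).

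This interval held 387 calls, 281 higher and 106 lower, with 192 named genes. AT5G55720, a pectate lyase family gene, rose 5.10-fold and AT4G05240 4.67-fold. AT1G80580 fell 3.1-fold, AT5G55430 2.25-fold, AT2G04063 2.23-fold and AT5G10970 2.19-fold. The falls of AT1G27020 (2.76-fold, adjusted p = 0.0330, and 0.0892 with the block) and AT3G13130 (2.46-fold, adjusted p = 0.0222, and 0.0713 with the block) were lost with the block. The inflorescence and flowering time list was lower as a group (adjusted p = 1.70e-05, adjusted p = 0.0814 with an estimated correlation), with 2 of 7 genes lower over all genes and 5 adjusted over the list alone. FD measured -0.19 (adjusted p = 0.0612). The auxin list was higher as a group (adjusted p = 0.0327, adjusted p = 0.146 with an estimated correlation), with GH3.3 and YUC6 called both over all genes and adjusted over the list alone. In the stamen and anther list 1 of 8 genes rose over all genes and adjusted over the list alone, and in the carpel and ovule list 1 of 6 rose over all genes, with 1 higher and 1 lower adjusted over the list alone, and neither list passed as a group (adjusted p = 0.167 and 0.189). With the block 228 features passed, with arrays scaled to 1 spread 667 did, and without sets 1, 2, 3 and 4 in turn 114, 129, 337 and 107 passed, with 89.5% higher in place of 72.6% when set 1 was left out, shares of lower calls if the direction is turned. When the 4 arrays were fitted alone 19 features passed.

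From day 4 to day 5 single genes of the pectate lyase, esterase and cutin synthase families were among the largest rises. AT5G55720 rose 8.88-fold (0.95 ± 0.21, adjusted p = 8.99e-04), the esterase family gene RXF26 8.01-fold (0.90 ± 0.40, adjusted p = 7.60e-04) and AT5G33370, of the cutin synthase family, 5.12-fold (0.71 ± 0.35, adjusted p = 0.00199), a mean of 2 probes that measured 0.37 and 1.05. MUTE rose 3.09-fold (0.49 ± 0.18, adjusted p = 0.0149), SPL/NZZ 1.46-fold (0.17 ± 0.067, adjusted p = 0.0112) and RCA, the activase of the carbon-fixing enzyme, 1.57-fold (0.20 ± 0.051, adjusted p = 0.0244). The stem-cell peptide gene CLV3 fell 2.02-fold (-0.30 ± 0.066, adjusted p = 0.0297, and 0.0922 with the set as a block), RBE fell 1.93-fold (-0.29 ± 0.10, adjusted p = 0.0160) and UFO 1.70-fold (-0.23 ± 0.065, adjusted p = 0.0186).

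There were 217 calls, 161 higher and 56 lower, 116 of them named. AT2G20870 rose 8.32-fold, AT3G12760 7.94-fold and AT3G56260 5.18-fold. AT1G80580 fell 2.75-fold, AT5G02540 2.12-fold, AT1G58310 2.08-fold and AT3G03270 2.00-fold (adjusted p = 0.0314, and 0.0671 with the block). The photosynthesis list was higher as a group (adjusted p = 1.42e-04, adjusted p = 0.146 with an estimated correlation), with 1 of 6 genes higher over all genes and 3 adjusted over the list alone. The shoot meristem and boundary list was lower (adjusted p = 0.0406, adjusted p = 0.146 with an estimated correlation) through CLV3, the 1 gene of 3 called over all genes and adjusted over the list alone, while LAS and LOB measured -0.06 and -0.01 (adjusted p = 0.529 and 0.973). The organ growth and polarity list was lower (adjusted p = 0.0464, adjusted p = 0.240 with an estimated correlation), with RBE alone called in both ways. The inflorescence and flowering time list was lower (adjusted p = 0.00962, adjusted p = 0.235 with an estimated correlation), with 0 of 7 genes called over all genes by limma (3 at an unadjusted p under 0.05) and 2 adjusted over the list alone. NGA3 rose 1.74-fold (adjusted p = 0.0238, and 0.0704 with the block), the 1 carpel and ovule gene called in both ways. WRKY53, of the touch and wounding list, rose 1.51-fold (adjusted p = 0.0121), the 1 gene of 3 called in both ways. With the block 114 features passed, with arrays scaled to 1 spread 93 did, and without sets 1, 2, 3 and 4 in turn 71, 35, 61 and 99 passed, with 88.6% higher in place of 74.2% when set 2 was left out, again shares of lower calls if the direction is turned. With arrays scaled CLV3, RBE, UFO, NGA3, RCA and MUTE lost their calls of this interval. With limma on the 4 arrays alone 0 passed, against 1452 at an unadjusted p under 0.05.

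**Figure D2:**
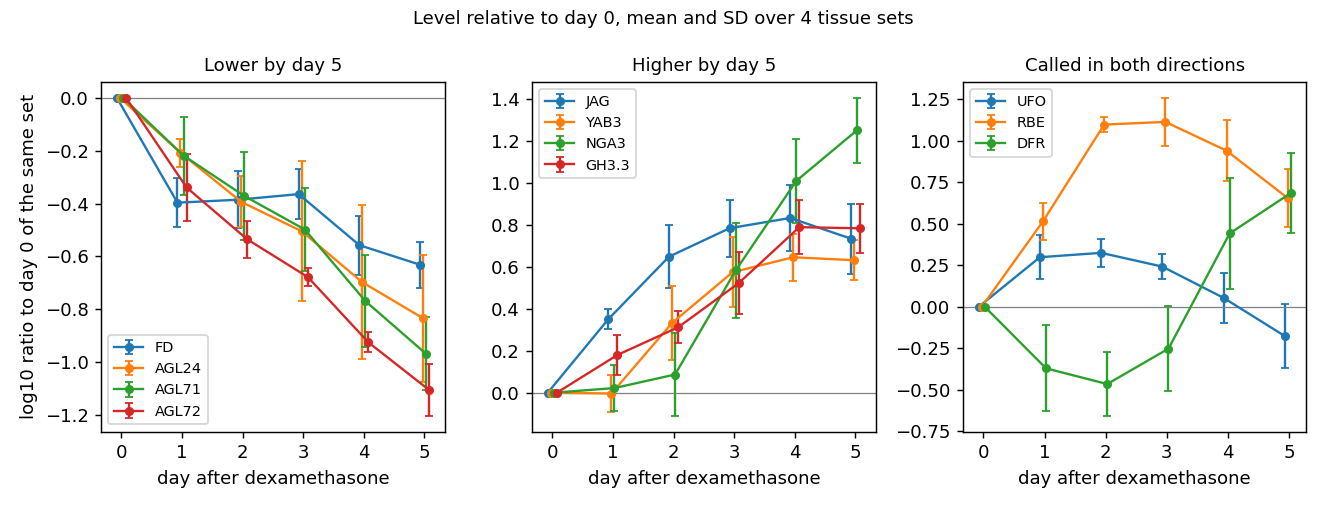
Log10 ratio to day 0 of the same tissue set (vertical axis) by day after dexamethasone (horizontal axis) for 11 genes in 3 panels; points are means and bars SDs over 4 sets, and the vertical scales differ between panels. AGL72 reached -1.10 and NGA3 1.3 on day 5, and RBE stood at 1.11 on day 3 and 0.65 on day 5.

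Day 5 against day 0, from the sum of the 5 ratios of each set, gives the net change over the course. NGA3 rose 17.8-fold (1.3 ± 0.16, SD, n = 4, adjusted p = 0.0120), REM22 137-fold (2.14 ± 0.22, adjusted p = 0.00904) and MUTE 31.6-fold (1.5 ± 0.34, adjusted p = 0.0191). JAG, RBE and YAB3 rose 5.42-fold, 4.52-fold and 4.28-fold, and SPL/NZZ rose 2.27-fold (0.36 ± 0.033, adjusted p = 0.0253). The MADS-box genes AGL72, AGL71 and AGL24 fell 12.7-fold (-1.10 ± 0.098, adjusted p = 0.00909), 9.28-fold (-0.97 ± 0.14) and 6.81-fold (-0.83 ± 0.24, adjusted p = 0.0318). FD fell 4.28-fold (-0.63 ± 0.087, adjusted p = 0.0163) and CLV3 3.05-fold (-0.48 ± 0.11, adjusted p = 0.0285, and 0.0759 as the sum of the interval coefficients). Of the cytokinin response regulators ARR16 rose 8.77-fold (0.94 ± 0.16, adjusted p = 0.0159) and ARR15 fell 4.09-fold (-0.61 ± 0.047, adjusted p = 0.0131, and 0.106 as that sum).

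The net comparison held 821 calls among 28615 features, 449 higher and 372 lower, 405 with a gene name. The largest rises among named genes were AT2G20870 (221-fold, 2.34 ± 0.55, adjusted p = 0.0195), AT5G22430 (179-fold, 2.25 ± 0.51, adjusted p = 0.0187) and AT5G55720 (140-fold, 2.15 ± 0.073). With 1 set left out the log10 change of AT2G20870 was 2.11 to 2.5 and that of AT5G22430 2.07 to 2.44, so their folds and order are uncertain. They were followed by REM22, AT4G16270 (68.0-fold), RXF26 (56.3-fold), AT2G42990 (34.2-fold), MUTE, AT1G15260 (30.9-fold) and AT5G16030 (30.0-fold). The largest fall, AT4G18230 (80.0-fold, n = 3), held 6 values at the limit of the scale and measured -0.91 with an adjusted p of 0.871 as the sum of the 5 interval coefficients. The next were AT1G27020 (24.3-fold), AT4G22490 (19.7-fold), AT3G13130 (15.6-fold), AGL72, AT1G19540 (12.6-fold), AT1G80580 (10-fold), AT2G04063 (9.71-fold), AGL71 and AT5G28000 (8.95-fold). The inflorescence and flowering time list was lower as a group (adjusted p = 1.42e-04, adjusted p = 0.235 with an estimated correlation), with 4 of 7 genes lower over all genes and 5 adjusted over the list alone. The organ growth and polarity list was higher (adjusted p = 8.21e-04, adjusted p = 0.202 with an estimated correlation), with 3 of 7 genes higher over all genes and 4 adjusted over the list alone. The photosynthesis list was higher (adjusted p = 0.00855, adjusted p = 0.333 with an estimated correlation) with 0 of 6 genes called over all genes by limma (4 at an unadjusted p under 0.05) and 4 adjusted over the list alone. In the carpel and ovule list NGA3 and SHI (2.05-fold, adjusted p = 0.0356) rose over all genes, with 3 higher and 1 lower adjusted over the list alone. In the auxin list GH3.3 rose 6.07-fold (adjusted p = 0.0158) and IAA29 fell 3.81-fold (adjusted p = 0.0217), with 4 higher and 1 lower adjusted over the list alone. SPL/NZZ was the 1 of 8 stamen and anther genes called over all genes, with 3 adjusted over the list alone, and CLV3 the 1 of 3 meristem genes called in both ways. These 4 lists did not pass as groups (adjusted p = 0.0847, 0.0986, 0.0604 and 0.0847). DFR rose 4.86-fold (0.69 ± 0.24, adjusted p = 0.0496, and 0.0643 as the sum of the interval coefficients). Without any 1 of the 4 sets 0 features passed in limma, where 3842, 3618, 4063 and 4721 had an unadjusted p under 0.05, and 329 passed with a dye term on the sums. With that term 14 of 34 named results lost their call: AT2G20870, AT5G22430, AT2G42990, AT4G22490, AT1G19540, AT1G80580, AT2G04063, AGL24, CLV3, RBE, SPL/NZZ, SHI, IAA29 and DFR. With arrays scaled to 1 spread AT4G22490, AT1G80580, CLV3 and DFR lost theirs. With values at the limits left out, a setting chosen after seeing the data, 1573 passed.

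Across the 5 intervals together 1522 features passed the test of a change in any interval, 768 of them named. The test of differences between intervals passed for 892 features, 431 of them named. With the set as a block these counts were 863 and 406, and without sets 1, 2, 3 and 4 in turn they were 470, 269, 1524 and 426, and 166, 45, 1030 and 193. RBE rose until day 2 and fell from day 4 to day 5, a fall not called with arrays scaled, and UFO rose by day 1 and fell from day 3 on, with a difference between intervals at adjusted p = 1.33e-05 and 8.21e-04. DFR fell from day 0 to day 1 and rose from day 3 to day 4 (adjusted p = 0.00117 for the difference). JAG (adjusted p = 0.00325), NGA3 (adjusted p = 0.00168) and FD (adjusted p = 0.00679) also passed the test of differences between intervals. For AGL24, AGL71 and AGL72 that test gave adjusted p = 0.866, 0.578 and 0.364. It treats arrays as independent, so noise in a day sample shared by neighbouring arrays may also give such differences. In simulated data with all noise carried by the samples, 50.5% of its calls were false. For the test of a change in any interval 31.4% were false. These shares do not bound those in the deposited values.

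The remaining lists gave few or no calls. Of 341 genes on 20 lists 65 were measured under a name, and 9 lists with at least 3 measured genes were tested in 54 tests, 15 of which passed, and 1 of them passed with an estimated correlation. The 6 DNA replication genes measured, 5 of them genes of histone H3.1, showed 0 calls in any comparison in limma, over all genes or adjusted over the list alone, with at most 2 at an unadjusted p under 0.05 in a comparison. The list's smallest adjusted p was 0.0604, from day 1 to day 2, when its median was 0.13. The stamen and anther list was nearest to a call for day 5 against day 0 (adjusted p = 0.0604) and from day 4 to day 5 (adjusted p = 0.0645), when 1 of 8 genes was called over all genes and 4 higher and 1 lower adjusted over the list alone. The touch and wounding list did not pass in any comparison (smallest adjusted p = 0.0687). Lists with 1 or 2 measured genes were not tested as groups: UFO for organ identity, AUR1 and AUR2 for the mitotic cell cycle, ARR15 and ARR16 for cytokinin, DFR for flavonoids, MUTE and FAMA for stomata, HSP22 for heat shock, GI for the clock, and TIP41 and EF1A as reference genes. AUR1 and AUR2 measured 0.08 and 0.07 for day 5 against day 0 (adjusted p = 0.707 and 0.657), HSP22 0.16 (adjusted p = 0.264), GI -0.06 (adjusted p = 0.591), and TIP41 and EF1A -0.10 and -0.04 (adjusted p = 0.499 and 0.964). FAMA, a later gene of the stomatal lineage, measured 1.39 with an adjusted p of 0.131. No gene of the gibberellin, jasmonate or vascular lists was measured under a name.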

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

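The tests on the share of lower calls from day 0 to day 1 and both tests of noise on opposite calls were chosen only after the results were seen, the held-out one in place of an earlier one whose outcome was known, and the others were fixed before. Of all features 71 were called higher in 1 interval and lower in another. In 8 of the genes that the naming rule picked a call in 1 interval had the opposite direction to a call in another, and the test of differences between intervals, by limma, passed in each, which follows largely from choosing genes with opposite calls. RBE (adjusted p = 1.33e-05) and UFO (adjusted p = 8.21e-04) rose early and fell late, though with arrays scaled to 1 spread their falls from day 4 to day 5 were not called, and DFR (adjusted p = 0.00117) and AT4G22870 (adjusted p = 7.49e-04) fell early and rose late. The other 4 were AT4G15765 (adjusted p = 3.70e-04), AT5G10970 (adjusted p = 1.03e-04), AT5G55430 (adjusted p = 1.03e-04) and AT5G43870 (adjusted p = 0.00198).

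In some comparisons 1 set of 4 lay far from the others, measured as the gap to its nearest neighbour divided by the whole range. For SHI from day 1 to day 2 this ratio was 0.894 (set 1 at 0.030, the others at 0.18 to 0.20), for AT4G15765 from day 2 to day 3 it was 0.916 (set 2 at -0.14, the others at -0.21 to -0.20), and for AT5G10970 from day 3 to day 4 it was 0.881 (set 2 at -0.54, the others at -0.29 to -0.26). From day 3 to day 4 the array of set 4 had 692 probes at the upper limit against 567 to 579 (ratio 0.904), and from day 0 to day 1 the array of set 3 had 31 probes at the lower limit against 3 to 7 (ratio 0.857). Over the 145 groups of 4 values examined, 5 stood out, and about 7.25 do so by chance.

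Other arrangements of the arrays were used to ask whether chance gives as many calls. For each interval the signs of the 4 arrays have 8 patterns, too few for a share under 0.05: 1 of 8, the real one, gave as many calls in day 0 to day 1 (950, highest other 1), day 1 to day 2 (329, highest other 0), day 2 to day 3 (120, highest other 0), day 3 to day 4 (387, highest other 0) and day 4 to day 5 (217, highest other 0). For day 5 against day 0 the real pattern gave 821 calls and the highest of the others 62, again 1 of 8. If arrays are independent, chance can be excluded for a change in any interval (1 of 100 patterns gave as many, 1522 against 314). The same holds for differences between intervals (1 of 100, 892 against 2). It also holds for the count of list tests that passed (1 of 40, 15 tests against 5). Most of the other sign patterns also had list tests that passed, so chance is not excluded for a single list call at the preset correlation. These arrangements break the tissue samples that neighbouring arrays of a set share, so they say nothing about noise carried by a sample. With such noise simulated data gave 44 false calls of a change in any interval and 97 of a difference between intervals.

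The first pattern is that calls of day 0 to day 1 were mostly lower, 621 of 950 in the likely direction of the ratios, and mostly higher if that direction is turned. Of the 262 calls of at least 2-fold 32.1% were higher (exact binomial 95% interval 26.5% to 38.1%). This argues against a small common shift from the centring of the arrays as the cause. A larger or uneven shift cannot be judged this way, because the normalization is unknown. Only 6 of the 950 calls held a value at a limit, which argues against such values. Leaving them out gave 32.8% of 999 calls higher (29.9% to 35.8%), but could hardly have moved the share. The binomial intervals here and below count features as independent, though all come from the same arrays. They do not measure the spread between tissue sets. A single tissue set cannot be told apart as the source: without set 2 46.7% of 195 calls were higher (39.5% to 53.9%), an interval that includes an even share, while without sets 1, 3 and 4 30.4%, 34.5% and 38.7% were higher. In the likely direction, a larger early fall than rise of transcripts after AP1 activation may be the reason and stays untested here, since no set without dexamethasone was analysed here.

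The second pattern is that 16 features were called in opposite directions from day 0 to day 1 and day 1 to day 2. Of these 5 were higher then lower and 11 lower then higher, where independent calls would give 5.92 in all. Each later pair of neighbouring intervals gave 0, where independent calls would give only 0.540, 0.524 and 1.15 in order. In the same 2 intervals 69 features were called in the same direction, where independent calls would give 4.99. Simulated data without change gave 0.1 features called in both, but with nothing changed hardly any call could arise there. The counts for independent calls leave out that all intervals share the estimate of spread of a feature. Neither is therefore a firm baseline for the 16 or the 69 features. Values at the limits argue against themselves, with 0 of the 16 at a limit on the 8 arrays. Noise in a day 1 sample, which both intervals share, cannot be told apart from a brief real change: of 28 features called in opposite directions from 3 sets, 12 went the same opposite way in the held-out set (42.9%; exact binomial 95% interval 24.5% to 62.8%), where noise alone would give about 1 of 3, and 22 of the 28 came from holding out set 3 (8 of 22) and 5 from set 4 (4 of 5). The earlier test took wider picks, features among the 500 largest changes of both intervals in 2 sets. Of these 31.7%, 18.9%, 13.9% and 15.5% went the same opposite way in the other sets. That test cannot decide either, because no share expected from noise alone is given for such picks. Most of these features also lie outside the 16.

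The third pattern is that 33 of 2003 interval calls rested on 1 dye assignment, with under 0.25 of the change left in the other, and 21 of them fell in day 0 to day 1 and 9 in day 1 to day 2. For the uneven split between the assignments, though not for the calls, a dye bias of the probe alike in all intervals is consistent with 23 of the 33 (exact binomial 95% interval 51.3% to 84.4%), whose dye coefficient on the other 16 arrays was at least 0.5 of that in the interval. Such a bias enters the 2 arrays of each assignment with opposite signs and cancels in the interval mean, unless a value stops at a limit. For AT3G30620, AT2G14415 and AT1G51890 that coefficient was 0.303, 0.160 and 0.165, smaller than a like bias would need. Values at the limits, seen in 10 of the 33 (15.6% to 48.7%), argue against being the whole cause. These 10 were, however, the largest changes of the 33 in size. The smallest of them, of an unnamed probe, was 0.737, and the largest change without such a value was 0.711, of AT3G30620. Such values therefore stay a possible cause for the largest changes. No biological explanation was tested.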

How the results depend on the processing

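The settings with values at the limits left out, with a dye coefficient for each interval, with calls of the same direction in every set and with the block in the list tests were chosen after the results were seen; the others were planned. Of 121 results for single named genes, none reversed under any of the alternatives run. Of 1980 alternative values, 1509 kept the call and direction and 471 lost the call. AT4G22870 from day 3 to day 4 was the 1 result that kept it under all of them. The largest rises and falls were picked for calls with the same sign in every set, so leaving out a set could hardly reverse them. The setting with calls of the same direction in every set largely repeats that rule. The 1.5-fold minimum cannot reverse a change. Leaving out set 1, 2 or 4 moved most counts, and leaving out set 3 moved 3 of 9. The range over the 4 leave-outs was 195 to 1040 for day 0 to day 1, 0 to 341 for day 1 to day 2, 0 to 193 for day 2 to day 3, 107 to 337 for day 3 to day 4, 35 to 99 for day 4 to day 5, 269 to 1524 for a change in any interval, 45 to 1030 for a difference between intervals, 0 to 0 for day 5 against day 0 and 12 to 15 for the gene lists. Fewer arrays are left there, and without a set the dyes no longer balance. In limma 3842, 3618, 4063 and 4721 features had an unadjusted p under 0.05 for day 5 against day 0 without sets 1, 2, 3 and 4, and 3477 and 1623 without set 2 for day 1 to day 2 and day 2 to day 3. With the tissue set as a replicate block the 5 intervals in order gave 605, 147, 57, 228 and 114 calls, a change in any interval 863 and a difference between intervals 406, and 15 of 87 named interval calls were lost. The block changed no list call: 15 list tests passed with it. The 4 arrays of an interval alone, with fewer residual degrees of freedom, gave 0, 5, 6, 19 and 0 calls, with 3537 and 1452 features at an unadjusted p under 0.05 in limma where 0 passed, and 2 of 87 named calls kept. Of named results 13 of 87 lost their call without a dye coefficient, 12 of 87 with one for each interval and 18 of 121 with arrays scaled. With 1 set left out the log10 change ranged over 0.92 to 1.36 for AT2G14415 and -1.24 to -0.79 for AT1G51890 from day 1 to day 2, 0.53 to 0.85 for AT5G55720 from day 3 to day 4, and 1.36 to 1.69 for AT2G42990 and -1.5 to -1.12 for AT4G22490 for day 5 against day 0. Without a dye coefficient 214 features passed from day 1 to day 2, and with arrays scaled to 1 spread 140, 667 and 93 passed from day 1 to day 2, day 3 to day 4 and day 4 to day 5. A dye coefficient for each interval gave 192 and 134 calls from day 1 to day 2 and day 4 to day 5, and 583 differences between intervals. A dye term on the sums left 329 calls for day 5 against day 0. Leaving out values at the limits raised that count to 1573, with 818 of the 819 calls tested in both fits shared, and for the other counts moved them by under 1.5 times. With an estimated correlation 1 of the list tests passed. The causes of the shifts with scaling, dye terms, limits and the block were not tested. Centring, the missing-value rules, single probes, robust eBayes, the 1.5-fold minimum, the sum of coefficients and the demand for the same direction in every set kept all counts within 1.5 times. The table holds no signal over background, so what dim spots limit is unknown.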

Other observations

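All tests in this part were chosen after the data were seen. Among named genes grouped by the stem of their symbol, the ATG genes, which act in autophagy, were lower as a group on day 5 than on day 0 in limma's camera test (adjusted p = 0.0112, and adjusted p = 0.942 with an estimated correlation). The 8 measured members, 7 of them of the ATG8 family, were all below 0, with arrays centred or scaled as well, and their median was -0.19, a factor of 1.54. ATG8B and ATG8G fell 1.84-fold (-0.26, SE 0.037; adjusted p = 0.0439) and 1.89-fold (-0.28, SE 0.040; adjusted p = 0.0463), while the other 6 were not called, ATG8H at -0.26 (adjusted p = 0.106) and ATG3 at -0.03 (adjusted p = 0.801). The PRA genes, of a family linked to vesicle transport, measured above 0 from day 2 to day 3 in 16 of 16 members, with arrays centred or scaled as well, by a median of 0.048, a factor of 1.12, and no member passed alone (smallest adjusted p 0.351). As a group they had an adjusted p of 0.0112 in the camera test, and adjusted p = 0.942 with an estimated correlation. Over 276 tests of 46 stems 2 passed, and with an estimated correlation none did.

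In the carpel and ovule list INO, a gene of the outer ovule layer, was counted and tested as the mean of 3 probes. These probes disagreed. By the sum over the course 2 of them measured 0.47 and 0.57 and the last -0.85, and their mean of 0.064 (SE 0.065; adjusted p = 0.681) describes none of them. The 2 probes of AT5G33370 differed in size, 2.16 against 0.54, and those of YAB3 measured 0.61 and 0.66. Of 547 control or unannotated spots, which entered no comparison, 530 had enough values to be tested. In limma 0 of them passed in any interval, and 142 of 2650 tests had an unadjusted p under 0.05.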
